A study of Homo sapiens with 8 samples.

How the data were processed

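The series holds RNA-seq of the human embryonic stem cell line SEES3 in 8 libraries: ZSCAN4 +/- and ZSCAN4 -/- cells, each as control or after transfection of synthetic DUX4 mRNA, with 2 libraries per group. Per the labels' protocols, total RNA was isolated with TRIzol, poly(A) RNA was selected and the libraries were made with a directional NEBNext kit. The labels call the libraries of a group biological replicates. Nothing in the sources used here says whether they come from separate cultures or days, so p-values measure the spread between these samples. Each genotype is 1 cell line, and the lines differ in their history of cloning and editing as well as in ZSCAN4.

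Per the file headers, each deposited table gives for 1 library a total read count per gene and an RPKM value, scaled for length and depth, that the authors computed, with RefSeq transcript accessions, gene symbols and positions. The reads were placed on hg19 per the submitters' processing notes. The aligner, the program that counted reads, the strand setting and any filter are not given in the sources used here. The counts were whole numbers without scaling and served for all main results; the deposited RPKM were used only for 1 alternative. All 23674 genes were present in each table, 0 without a gene name. Symbols that a spreadsheet had turned into dates (28) were restored by accession for 27. Of 604 genes on the fixed lists 600 were matched, 9 of them through an accession.

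Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr on the 4 groups (13868 tested), libraries were scaled with TMM (factors of 1.04 to 1.05 in controls and 0.948 to 0.962 after DUX4), and 1 quasi-likelihood model with robust settings held the 4 groups, with 4 residual degrees of freedom and a common biological coefficient of variation of 0.052. The contrasts were DUX4 against control in each line, -/- against +/- in controls and after DUX4, and the difference of the DUX4 effects between the lines. P-values were adjusted by Benjamini-Hochberg over the tested genes of a contrast, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given ± SE, taken from the fold change and the F statistic, and levels as TMM-scaled CPM ± SD of 2 libraries. Where a group had 0 reads, folds are lower bounds with 3 reads over the group in place of 0; with 1 to 3 reads, they are ratios with an exact counting interval.

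The tests, contrasts, 25 gene lists and the rule for naming genes were fixed before the data were examined, as were the alternatives listed below except where said. Genes named were ZSCAN4 and DUX4, the 10 largest increases and decreases of each comparison among called genes with at least 5 CPM in the higher group and both libraries of 1 group beyond both of the other (the last not asked of the difference between lines), up to 4 members of each list by p and members that went against it, and POU5F1, SOX2 and NANOG. Clone names, open reading frame names and small RNAs were left out. Some genes that met this rule are not reported here. The lists covered DUX4 targets (mostly single-copy, and multicopy), pluripotency, naive pluripotency, stress and immediate early responses, decay substrates, histones, ribosomal proteins, mitochondrially encoded genes, DNA methylation, telomere factors, metabolism, cell cycle, the ZSCAN family, and markers of 5 other cell types (neuroectoderm, mesoderm, endoderm, trophectoderm and fibroblast). A list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation between genes estimated from the data. Lists share members (KLF4, ATF3, GADD45A and others), so their tests are not independent.

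Alternatives were DESeq2 size factors, no filter, a stricter filter (5 CPM in 2 libraries), the DESeq2 1.42.0 Wald test, limma-voom, a block for the replicate number, only the 2 groups compared, a threshold of 2-fold, and each library left out in turn. Chosen after seeing the data were library totals alone, a correction for GC content and transcript length together, leaving out genes that overlap another on the same strand, and limma on the log2 of the deposited RPKM. Ranges of adjusted p over alternatives leave out the 2-fold threshold, which has no p of its own. GC values and lengths were matched for 98.1% of tested genes; over these, the Spearman correlation of the log2 fold change with GC content was 0.096 and -0.129 for DUX4 in +/- and -/- cells, 0.238 and -0.181 between the lines in controls and after DUX4, and -0.323 for the difference of the effects. On the same strand 2967 genes overlapped another, 1197 of them tested, and since the strand setting is not given, reads of such genes may belong to the neighbour.

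The pipeline was tested on simulated data of 13432 genes. These were drawn from the gene means of the +/- controls and the library sizes of these samples, with genes changed only in the -/- DUX4 group. It called 0 unchanged genes for DUX4 in +/- cells and between controls, where nothing was changed. The simulation held no broad response to DUX4, so it does not test how scaling copes with one. For DUX4 in -/- cells it recovered 68.7% of genes changed by 1.5-fold, 90.9% by 2-fold and 92.4% by 4-fold, with 14 unchanged genes called. For -/- against +/- after DUX4 the shares were 73.1%, 92.4% and 95.5%, with 17 unchanged genes called, and for the difference of the effects 44.8%, 78.8% and 83.3%, with 9. Library totals lay between 7813922 and 10572230 reads, so that 3 reads over a group corresponded to 0.149 and 0.174 CPM in +/- controls and DUX4 libraries and 0.14 and 0.19 CPM in the -/- groups. No single library was tested for standing apart from its group. DESeq2 left the adjusted p of some genes empty by its own filter, and these count as not called. A planned test of sequence motifs near gene starts was not made, as the genome sequence was not used here.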

Results

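RNA was measured in SEES3, a human embryonic stem cell line, in 8 libraries of poly(A)-selected RNA. In the line called ZSCAN4 +/- here, an Emerald GFP sequence replaces 1 allele of ZSCAN4 and the other allele is intact. In the line called ZSCAN4 -/-, CRISPR-Cas9 has disrupted that other allele. ZSCAN4 is a zinc finger gene expressed in cleavage-stage embryos, and DUX4 is the homeobox transcription factor that switches on many genes of that stage. Each line was kept as a control or transfected with synthetic DUX4 mRNA, which gives 4 groups of 2 libraries. Any treatment of the controls is not described here, so changes after DUX4 mRNA may include effects of transfection itself. The libraries held 7813922 to 10572230 reads in genes, and 6.07% to 6.40% of them lay in mitochondrially encoded genes. The first principal component of log2 CPM held 77.4% of the variance and separated DUX4 from control libraries, and the second held 5.81%.

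The targeted gene was read first. ZSCAN4 (NM_152677, chromosome 19, 58180303 to 58190520, plus strand, hg19) had 0 reads in both +/- control libraries, and 2 and 0 reads in the -/- controls. After DUX4 its level was 573 ± 51.5 CPM in +/- cells and 529 ± 42.8 CPM in -/- cells (SD, n = 2 each). The log2 difference of the -/- from the +/- line after DUX4 was -0.12 ± 0.08 (SE; edgeR adjusted p = 0.736). A count per gene does not show whether the RNA holds the CRISPR-Cas9 change, so these levels do not check the genotype labels. The DUX4 gene itself had 0 reads in all 8 libraries, and its copy DUX4L2 had 0 to 2 reads per library. The dose of DUX4 mRNA per library could not be read from the counts.

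**Figure D1:**
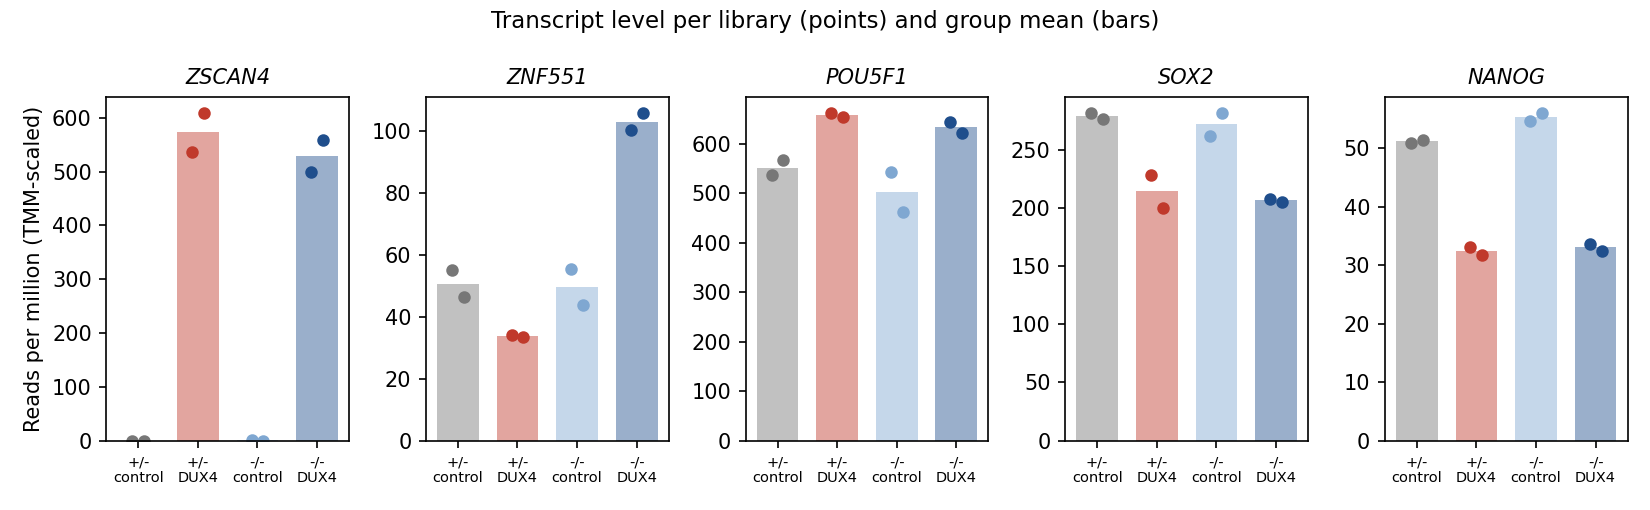
Transcript level of ZSCAN4, ZNF551, POU5F1, SOX2 and NANOG in TMM-scaled CPM, with 1 point per library and bars for the mean of the 2 libraries in each group. ZSCAN4 lies at 0 to 0.096 CPM on average in the control groups and at 573 and 529 CPM after DUX4, and ZNF551 after DUX4 lies at 33.8 CPM in +/- and 103 CPM in -/- cells.

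The first comparison asks which genes DUX4 mRNA changed in cells with an intact ZSCAN4 allele. It raised genes of the cleavage-stage embryo, some of them from almost no reads. Among the 10 largest increases were the homeobox genes LEUTX (at least 3202-fold higher, 477 ± 50.8 CPM) and DUXA, the histone demethylase gene KDM4E (at least 2988-fold), and KLF17 (at least 2315-fold), a transcription factor gene of naive pluripotent cells. ZSCAN4 rose at least 3842-fold and KHDC1L at least 2865-fold. DUXA went from 1 read over both controls to 613 ± 65.4 CPM, a ratio of 12210 (95% counting interval 2192 to 482500). The remaining 4 belong to families of near-identical copies whose reads may be shared: RFPL2 (at least 4772-fold higher), TRIM43 (at least 1396-fold), TRIM43B (at least 1184-fold) and PRAMEF1 (at least 718-fold). Of the fixed list of mostly single-copy DUX4 targets, 18 of 19 tested members rose and 1 did not pass (camera adjusted p = 1.42e-263; adjusted p = 0.00215 with an estimated correlation). Its median log2 fold change was 9.25, also with 7 members at their lower bound. Members with reads in controls included CCNA1, a cyclin gene (7.03 ± 0.10), and ZNF296 (4.03 ± 0.08). Of the targets in multicopy families, 29 of 31 rose over all genes and 31 when adjusted over the list alone (camera adjusted p = 4.47e-209; adjusted p = 0.00422 with an estimated correlation). Their median was 11.30 as fitted and 7.89 with 26 members at their bound. The filter kept 19 of 27 matched single-copy targets and 31 of 43 matched multicopy targets. A member without control reads could pass it only through reads after DUX4, so the shares that rose were partly fixed by the filter.

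Genes of the immediate early and integrated stress responses rose with them. JUN and FOS, the subunits of AP-1, rose by 3.77 ± 0.11 and 2.98 ± 0.09 on the log2 scale, and EGR1, a zinc finger transcription factor gene, by 4.71 ± 0.15 (SE, n = 2 against 2; edgeR adjusted p = 3.02e-18, 3.92e-18 and 6.31e-18). In the immediate early list 18 of 20 genes rose, 19 adjusted over the list alone, with a median of 1.63 (camera adjusted p = 1.43e-44; adjusted p = 0.00215 with an estimated correlation). In the list of the ATF4 integrated stress response 18 of 23 rose, 1 fell and 4 did not pass, with a median of 0.51 (camera adjusted p = 1.34e-12; adjusted p = 0.00797 with an estimated correlation). ATF3 rose by 3.21 ± 0.10, CTH, an enzyme of cysteine synthesis, by 2.22 ± 0.11 and PPP1R15A, a phosphatase subunit that reverses the eIF2 alpha mark, by 2.24 ± 0.10. The naive pluripotency list, which shares KLF17, ALPPL2, ARGFX and KHDC3L with the list of DUX4 targets, had 8 of 11 higher, 0 lower and a median of 2.43 (camera adjusted p = 5.42e-36; adjusted p = 0.0125 with an estimated correlation). KLF4 and KLF5 in it rose by 2.10 ± 0.10 and 3.60 ± 0.18. The filter kept 11 of its 18 matched members, so its share may be raised in the same way as those of the DUX4 targets. The p53 list split: CDKN1A, a cell cycle inhibitor gene, rose by 2.02 ± 0.12, GADD45A by 2.68 ± 0.10, and PMAIP1, a pro-apoptotic gene, by 1.46 ± 0.07, while 8 of 26 members fell and 5 rose. Its median was -0.22 and its mean -0.07, whereas camera ranked it upward without a call (adjusted p = 0.562).

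Of 21 cholesterol synthesis genes 19 rose, 2 did not pass and the median was 0.45 (camera adjusted p = 5.37e-08; adjusted p = 0.0739 with an estimated correlation). HMGCS1 rose by 0.68 ± 0.06. Of 28 glycolysis and hypoxia genes 17 rose, 19 with 1 lower adjusted over the list alone, and the median was 0.26 (camera adjusted p = 5.57e-07; adjusted p = 0.058 with an estimated correlation). The glucose transporter gene SLC2A3 rose by 1.07 ± 0.06 and PFKFB3 by 1.42 ± 0.08. Of 25 snoRNA host genes and other substrates of nonsense-mediated decay 15 rose and 10 did not pass, 1 being lower adjusted over the list alone, with a median of 0.34 (camera adjusted p = 3.84e-05; adjusted p = 0.153 with an estimated correlation). The host gene SNHG12 rose by 1.45 ± 0.12, though its reads may include the snoRNAs that it overlaps, and GADD45B by 2.59 ± 0.12. Cytosolic ribosomal protein genes were higher in 29 of 39, 32 adjusted over the list alone, by a median of 0.24 (camera adjusted p = 0.00101; adjusted p = 0.418 with an estimated correlation). Of 15 heat shock genes 10 rose, with a median of 0.24 (camera adjusted p = 0.0247; adjusted p = 0.153 with an estimated correlation). That call ended with library totals alone as scaling (adjusted p = 0.0865) and without +/- DUX4 replicate 1 (0.0539), with 0.000479 to 0.0865 over all alternatives.

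Core pluripotency genes moved apart, by less than 1 on the log2 scale. NANOG fell to 32.4 ± 0.976 from 51.2 ± 0.424 CPM (-0.66 ± 0.09, adjusted p = 2.48e-06) and SOX2, which overlaps SOX2-OT, to 214 ± 20.1 from 279 ± 3.72 CPM (-0.38 ± 0.07, adjusted p = 9.77e-05). POU5F1 went from 551 ± 21.3 to 658 ± 5.31 CPM (0.26 ± 0.06, adjusted p = 0.00361). That call ended with library totals alone (log2 0.12, adjusted p = 0.136), with the deposited RPKM (0.05, adjusted p = 0.593) and without +/- control replicate 1 (0.21, adjusted p = 0.0963; 4.03e-07 to 0.593 over all alternatives). In the list of shared and primed pluripotency genes 14 of 29 fell, 15 adjusted over the list alone, and 3 rose, with a median of -0.24 (camera adjusted p = 0.00819; adjusted p = 0.204 with an estimated correlation). Markers of other cell types were mixed. Mesoderm and primitive streak markers were higher in 4 of 8 and lower in 1, with a median of 0.81 (camera adjusted p = 0.000659; adjusted p = 0.068 with an estimated correlation). That call ended without a filter on low counts (adjusted p = 0.0527, in a range of 6e-05 to 0.0527). EOMES, a T-box gene of the primitive streak, rose by 4.12 ± 0.14. Neuroectoderm markers were higher in 7 of 12, with a median of 0.71 (camera adjusted p = 0.0308; adjusted p = 0.153 with an estimated correlation), and SOX3 rose by 1.39 ± 0.12. Trophectoderm and amnion markers were higher in 2 of 9, TFAP2C (1.78 ± 0.07) and IGFBP3 (1.78 ± 0.14), with a median of 0.11 (camera adjusted p = 0.0247; adjusted p = 0.394 with an estimated correlation). The neuroectoderm call ended without either +/- control library (adjusted p = 0.062 and 0.056), either +/- DUX4 library (0.0693 and 0.0845) or either -/- DUX4 library (0.0697 and 0.0675), and the trophectoderm call without +/- control replicate 1 (0.066) or +/- DUX4 replicate 2 (0.0554). The first ended also with the stricter filter (0.0504) and in DESeq2 (0.076), and the second with no filter (0.0902). Over all alternatives the neuroectoderm list had 0.00476 to 0.0845 and the trophectoderm list 0.00581 to 0.0902.

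The other lists were not called in +/- cells. By camera adjusted p, cell cycle genes (0.0572; 10 of 32 higher, 1 lower) and endoderm markers (0.0627; 2 of 6 higher, 4 lower, median -0.55 against a mean of 0.97) came closest. Within them CCNA2, a cyclin gene, rose by 1.06 ± 0.06, CXCR4, a chemokine receptor gene, by 7.05 ± 0.18, and KIT fell by 0.64 ± 0.09. DNA methylation factors had 0.153 (3 of 15 higher, 2 lower, median -0.01 against a mean of 0.34, TET1 -0.47 ± 0.07). Fibroblast and mesenchymal markers had 0.174 (3 of 12 higher, 1 lower) and replication-dependent histones 0.22 (5 of 13 higher). NF-kB genes had 0.264 (2 of 10 higher, median -0.10 against a mean of 0.23) and mitochondrially encoded genes 0.307 (6 of 13 higher, median 0.15). Telomere and recombination factors had 0.33 (2 of 19 higher, 2 lower). The ZSCAN family and its co-repressors had 0.33 (4 of 21 higher, 6 lower, median -0.17 against a mean of 0.57) and interferon and RNA-sensing genes 0.927 (4 of 17 higher, 2 lower, ranked downward with a mean of 0.43). For other lists the members higher and lower adjusted over the list alone were as follows: p53 (5 and 10), telomere (2 and 1), ZSCAN family (4 and 7) and fibroblast (6 and 1).

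In +/- cells 2104 of 13868 tested genes were higher and 1369 lower after DUX4 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 605 and 85 of them by at least 2-fold. Of the 3473, 3472 had both libraries of 1 group above both of the other. By chance 33.3% of genes would be so separated. A call with 2 libraries per group nearly requires it, so it adds no support here or in the later comparisons. The 9 named decreases were smaller than the increases: ZNF441, a zinc finger gene (-1.61 ± 0.28, adjusted p = 8.76e-05), GRPR, a gastrin-releasing peptide receptor gene (-1.37 ± 0.28), ZNF425 (-1.34 ± 0.19), C1QTNF6 (-1.26 ± 0.17), and ARHGAP29 (-1.23 ± 0.20). The others were EMILIN3 (-1.18 ± 0.25), VWC2 (-1.14 ± 0.22), SCAND3 (-1.14 ± 0.20) and PDIK1L (-1.12 ± 0.27). EMILIN3 was not called without +/- DUX4 replicate 1 (adjusted p = 0.0694), nor PDIK1L without +/- DUX4 replicate 2 (0.0652). The balance of higher and lower genes rests on the scaling. With library totals in place of TMM the median of all genes moved by -0.13 and 1322 genes were higher and 3426 lower, so that 27.8% of calls were higher against 60.6%. With the deposited RPKM the median moved by -0.19, with 930 higher and 4360 lower (17.6%). The medians of the mitochondrially encoded genes (0.15), cell cycle genes (0.11), trophectoderm markers (0.11) and fibroblast markers (0.13) were smaller than the second shift. The number of lower genes fell to 689 and 742 without the 1st or 2nd +/- control library, to 752 and 737 without the 1st or 2nd +/- DUX4 library, and to 586 in DESeq2, with 1502 higher.

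The same question in ZSCAN4 -/- cells gave 5 of the same 10 largest increases: DUXA, TRIM43, TRIM43B, ZSCAN4 and LEUTX. This ranking turns on stray control reads. After DUX4, RFPL2 was at 711 CPM in +/- and 754 CPM in -/- cells, and KDM4E at 445 and 529 CPM. KHDC1L was at 427 and 406 CPM, KLF17 at 345 and 346 CPM and PRAMEF1 at 107 and 102 CPM. These genes had 0 CPM in +/- controls and 0.048 to 0.271 CPM in -/- controls. DUXA rose at least 4783-fold to 668 ± 83.2 CPM, and TPRX1, another homeobox gene, at least 1870-fold to 261 ± 21.5 CPM. ZSCAN5B, a zinc finger gene related to ZSCAN4, rose at least 658-fold. ZSCAN4 rose by a ratio of 5663 (95% counting interval 1567 to 46770) and LEUTX by 5304 (1468 to 43800), each against 2 control reads. The other 5 may share reads with copies or an overlapping gene: TRIM43 (at least 1585-fold higher), TRIM49 (at least 1564-fold), TRIM43B (at least 1408-fold), TRIM51 (at least 532-fold) and FRG2C (at least 1698-fold). FRG2C passed narrowly (edgeR adjusted p = 0.0413) and not without +/- DUX4 replicate 1 (0.18) or 2 (0.185) or -/- control replicate 1 (0.0718) or 2 (0.0779). It was not called either with no filter (0.0644) or with only the 2 groups compared (0.183). Of the single-copy targets 18 of 19 rose (median 9.46, or 8.96 with 5 members at their bound; camera adjusted p = 1.56e-254, and adjusted p = 0.00264 with an estimated correlation). Of the multicopy targets 31 of 31 rose (median 10.74, or 8.20 with 23 at their bound, camera adjusted p = 5.24e-199, and adjusted p = 0.00567 with an estimated correlation). The limit that the filter sets in +/- cells holds in -/- cells for both target lists and the naive pluripotency list.

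Immediate early genes were higher in 16 of 20, with 1 lower adjusted over the list alone (median 1.60; camera adjusted p = 1.03e-44; adjusted p = 0.00264 with an estimated correlation). JUN was at 3.95 ± 0.11, FOS at 3.18 ± 0.09 and EGR1 at 4.87 ± 0.12. Genes of the integrated stress response were higher in 16 of 23, 17 adjusted over the list alone, and lower in 2 (median 0.52; camera adjusted p = 5.09e-12; adjusted p = 0.00877 with an estimated correlation), with ATF3 at 3.42 ± 0.10. Naive pluripotency genes were higher in 8 of 11, with 1 lower adjusted over the list alone (median 3.20; camera adjusted p = 2.79e-36; adjusted p = 0.0128 with an estimated correlation), with KLF4 at 2.75 ± 0.10. Cholesterol synthesis genes were higher in 16 of 21, 17 adjusted over the list alone (median 0.35; camera adjusted p = 4.41e-05; adjusted p = 0.137 with an estimated correlation). Glycolysis and hypoxia genes were higher in 15 of 28 with 1 lower, 16 and 3 adjusted over the list alone (median 0.16; camera adjusted p = 1.46e-05; adjusted p = 0.0792 with an estimated correlation). SnoRNA hosts and other decay substrates were higher in 13 of 25 with 2 lower, 15 and 2 adjusted over the list alone (median 0.32; camera adjusted p = 2.94e-05; adjusted p = 0.137 with an estimated correlation). CCNA2 rose by 1.07 ± 0.06 and UBE2C, which acts in mitotic exit, by 1.20 ± 0.07. Cell cycle genes were higher in 16 of 32, 19 with 3 lower adjusted over the list alone (median 0.18; camera adjusted p = 0.0272; adjusted p = 0.408 with an estimated correlation). That call ended with library totals alone (adjusted p = 0.139) and with only the 2 groups compared (0.0514; 6.05e-05 to 0.139 over all alternatives).

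Pluripotency genes fell in 13 of 29, 15 adjusted over the list alone, and rose in 4 (median -0.18; camera adjusted p = 0.034; adjusted p = 0.35 with an estimated correlation). The call ended with only the 2 groups compared (adjusted p = 0.0514), without overlapping genes (0.0613) and without -/- DUX4 replicate 1 (0.0681, in a range of 0.000713 to 0.0681 over all alternatives). The replicate block ended the call of this list as well. NANOG went from 55.4 ± 0.923 to 33.1 ± 0.837 CPM (-0.74 ± 0.09, adjusted p = 2.96e-07) and SOX2 from 272 ± 13.9 to 207 ± 2.06 CPM (-0.40 ± 0.07, adjusted p = 5.1e-05). POU5F1 went from 502 ± 58.2 to 632 ± 15.6 CPM (0.33 ± 0.06, adjusted p = 0.000268), not called with the deposited RPKM (adjusted p = 0.221). Mesoderm and primitive streak markers were higher in 4 of 8 and lower in 1, 5 and 2 adjusted over the list alone (median 0.78; camera adjusted p = 4.62e-05; adjusted p = 0.0467 with an estimated correlation). That call ended without a filter on low counts (adjusted p = 0.12, median -0.34, in a range of 7.56e-07 to 0.12). EOMES rose by 4.30 ± 0.13. Trophectoderm and amnion markers were higher in 2 of 9 (median 0.07; camera adjusted p = 0.0407; adjusted p = 0.46 with an estimated correlation). That call was lost with no filter (adjusted p = 0.12), in limma-voom (0.146), with only the 2 groups compared (0.0514), with the deposited RPKM (0.143), without +/- DUX4 replicate 1 (0.052) and without -/- DUX4 replicate 1 (0.0915; 0.0185 to 0.146 over all alternatives). The trophectoderm call was lost with the replicate block too, and the median of the list turned to -0.18 with the deposited RPKM. Endoderm markers had 1 of 6 higher, CXCR4 (7.65 ± 0.17), and 4 lower. Camera called the list upward (adjusted p = 0.0407; adjusted p = 0.408 with an estimated correlation), with a mean of 0.92, while its median was -0.50. That call ended with no filter (adjusted p = 0.805), in DESeq2 (0.539) and limma-voom (0.42), with only the 2 groups compared (0.0521), without overlapping genes (0.0613), with the deposited RPKM (0.767) and with the replicate block. It ended also without either +/- DUX4 library (adjusted p = 0.0591 and 0.0685), without -/- control replicate 2 (0.0567) and without -/- DUX4 replicate 1 (0.0691; 0.0153 to 0.805 over all alternatives).

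The remaining lists were not called in -/- cells. Their camera adjusted p began at 0.0664 for DNA methylation factors (2 of 15 higher, 2 lower) and 0.0909 for heat shock genes (8 of 15 higher, 2 lower). Next were fibroblast and mesenchymal markers (0.118; 4 of 12 higher, 1 lower), ribosomal protein genes (0.15; 15 of 39 higher, 17 adjusted over the list alone, median 0.13) and mitochondrially encoded genes (0.181; 7 of 13 higher). Neuroectoderm markers had 0.283 (5 of 12 higher, 2 lower, SIX3 at -0.66 ± 0.12), NF-kB genes 0.286 (3 of 10 higher, 2 lower) and the p53 list 0.418 (4 of 26 higher, 10 lower, CDKN1A at 2.23 ± 0.11). The last were histones (0.418; 4 of 13 higher), telomere factors (0.418; 2 of 19 higher, 5 lower), the ZSCAN family (0.445; 3 of 21 higher, 6 lower) and interferon genes (0.98; 3 of 17 higher, 1 lower). The median was negative while camera ranked the list upward for p53, NF-kB and ZSCAN family genes, and the reverse held for interferon genes, with a median of 0.01 and a mean of 0.48. For other lists the members higher and lower adjusted over the list alone were as follows: p53 (4 and 12), NF-kB (3 and 3), ZSCAN family (3 and 7), neuroectoderm (6 and 2) and fibroblast (5 and 1).

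In -/- cells 2150 genes were higher and 1643 lower after DUX4 (edgeR adjusted p under 0.05), 663 and 117 by at least 2-fold, and in all 3793 both libraries of 1 group lay above both of the other. The largest named decreases included ZNF441 (-1.66 ± 0.28), VWC2 (-1.63 ± 0.22, adjusted p = 3.39e-06), CLDN11, a tight junction gene (-1.60 ± 0.23), C1QTNF6 (-1.52 ± 0.16), PDIK1L (-1.43 ± 0.27), ZNF584 (-1.34 ± 0.23) and FOXJ1, the regulator of motile cilia (-1.30 ± 0.18). URGCP-MRPS24 (-2.23 ± 0.46), P2RX5-TAX1BP3 (-1.61 ± 0.35) and ZNF177 (-1.38 ± 0.26) overlap other genes on the same strand, so their reads are uncertain. With library totals alone the median of all genes moved by -0.14 and 1386 were higher and 3975 lower (25.9% of calls higher against 56.7%), and with the deposited RPKM, moved by -0.21, 949 and 5132 (15.6%). The medians of the glycolysis (0.16), cell cycle (0.18), trophectoderm (0.07), mitochondrially encoded (0.17) and ribosomal protein (0.13) lists were smaller than the RPKM shift. The number of lower genes fell to 911 and 760 without the 1st or 2nd -/- DUX4 library, and to 648 in DESeq2, with 1628 higher.

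The responses of the 2 lines share no library, so they could be set against each other gene by gene. Both lines raised 1545 of the same genes, where independent lists would share 326.2, and lowered 783, where they would share 162.2; 2 genes higher in +/- cells were lower in -/- cells and 2 went the other way. Across the 4755 genes called in either line with more than 3 reads in each control group, the slope of the -/- on the +/- log2 fold change was 0.961 and Pearson's r 0.908, with 94.8% in the same direction and 90.6% within 0.5 of each other; the slope of the +/- on the -/- values was 0.858. Most of these changes were small: among the 732 that moved at least 2-fold in either line, 60.8% lay within 0.5 of each other (quartiles of the difference -0.342 and 0.396), with slopes of 0.947 and 0.837 and r = 0.89. CCNA1 rose by 7.03 ± 0.10 and 7.30 ± 0.10, JUN by 3.77 ± 0.11 and 3.95 ± 0.11, and NANOG changed by -0.66 ± 0.09 and -0.74 ± 0.09, in +/- and -/- cells in turn. Over all 13868 genes r was 0.89 and the slope 0.89. Genes are not independent replicates, so no p is given for these values.

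**Figure D2:**
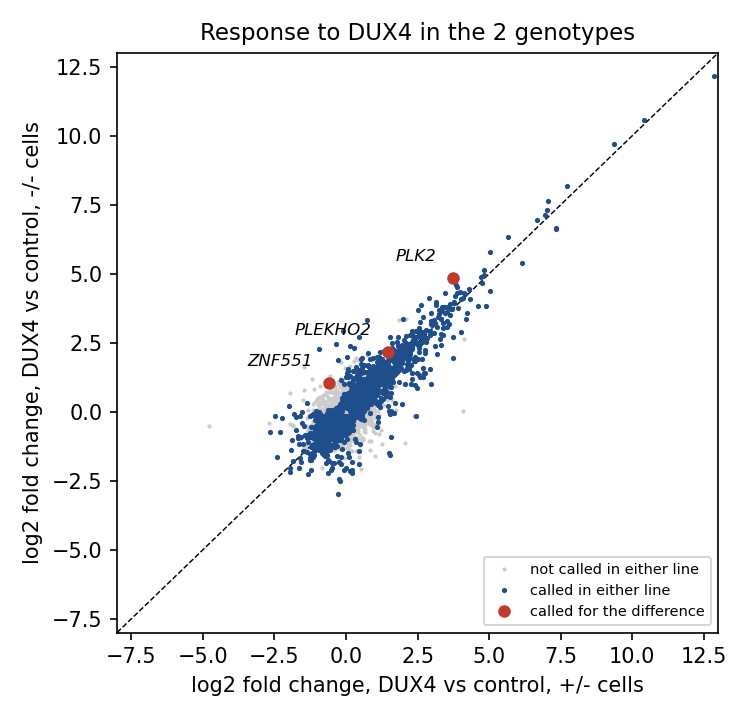
Log2 fold change of DUX4 against control in +/- cells (horizontal) and in -/- cells (vertical), with 1 point per gene for 13657 genes with more than 3 reads in every group, and a dashed line where both are equal. The 4749 genes called in either line lie along the line, and ZNF551, PLK2 and PLEKHO2, called for the difference, lie above it by 1.64, 1.13 and 0.70.

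The next comparison asks what loss of the remaining ZSCAN4 allele went with before DUX4, when ZSCAN4 was at 0 to 2 reads. The -/- controls held more RNA of genes of the early nervous system. PRTG, a cell surface gene of early neural development, was at 29.2 ± 0.428 CPM against 5.58 ± 0.247 in +/- controls (2.39 ± 0.15, adjusted p = 1.65e-09; NM_173814, chromosome 15, 55903739 to 56035177, hg19). PAX7, a neural crest and muscle regulator, was at 7.69 ± 0.422 against 1.69 ± 0.019 CPM (2.18 ± 0.28), and MAP2, a neuronal microtubule gene, at 11 ± 0.905 against 2.94 ± 0.067 CPM (1.90 ± 0.20). The other increases were QPCT (2.53 ± 0.31), the netrin receptor gene UNC5C (2.33 ± 0.34), the cadherin gene CDH6 (1.95 ± 0.18), and the semaphorin gene SEMA6D (1.92 ± 0.24). TFPI, an inhibitor of coagulation (1.61 ± 0.22), the eye field gene SIX6 (1.39 ± 0.27) and the neuropeptide-processing enzyme CPE (1.34 ± 0.14) were higher too. TFPI was not called with the deposited RPKM (adjusted p = 0.077), nor SIX6 in DESeq2 (0.13). Of 12 neuroectoderm markers tested 6 were higher, 7 adjusted over the list alone, and 0 lower, with a median of 0.80 (camera adjusted p = 3.07e-19; adjusted p = 0.015 with an estimated correlation). SOX3 was higher by 1.16 ± 0.12 and SIX3 by 1.08 ± 0.13.

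Genes lower in -/- controls were led by MCCC2, an enzyme subunit of leucine breakdown, at 46.4 ± 2.35 against 96.2 ± 5.31 CPM (-1.05 ± 0.07, adjusted p = 5.45e-09; NM_022132, chromosome 5, 70883115 to 70954530, hg19). PUS7L (-0.87 ± 0.11), the linker histone gene H1F0 (-0.85 ± 0.12), JRK (-0.84 ± 0.10), NGRN (-0.75 ± 0.07) and NODAL, a ligand that acts in pluripotent cells and in the primitive streak (-0.72 ± 0.10), were lower too. TNFSF11 (-0.88 ± 0.21), PLK2 (-0.71 ± 0.14), WDR72 (-0.70 ± 0.12) and GNA14 (-0.68 ± 0.15) were also called. Their calls, and that of SIX6, ended without +/- control replicate 2 (adjusted p = 0.245, 0.159, 0.1, 0.154 and 0.202). TNFSF11 and GNA14 were lost also without +/- control replicate 1 (0.216 and 0.236) or -/- control replicate 2 (0.0551 and 0.0571), and TNFSF11 without -/- DUX4 replicate 2 (0.0509). Calls were lost also in DESeq2 for TNFSF11 (adjusted p = 0.48) and GNA14 (0.307), in limma-voom for TNFSF11 (0.0575) and PLK2 (0.082), and with only the 2 groups compared for TNFSF11 (0.0847) and PLK2 (0.061). The same held with the deposited RPKM for JRK (0.0971), TNFSF11 (0.0777), WDR72 (0.124) and GNA14 (0.117). POU5F1 (-0.14 ± 0.06, adjusted p = 0.358), SOX2 (-0.04 ± 0.06, adjusted p = 0.865) and NANOG (0.12 ± 0.08, adjusted p = 0.562) did not pass.

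**Figure D3:**
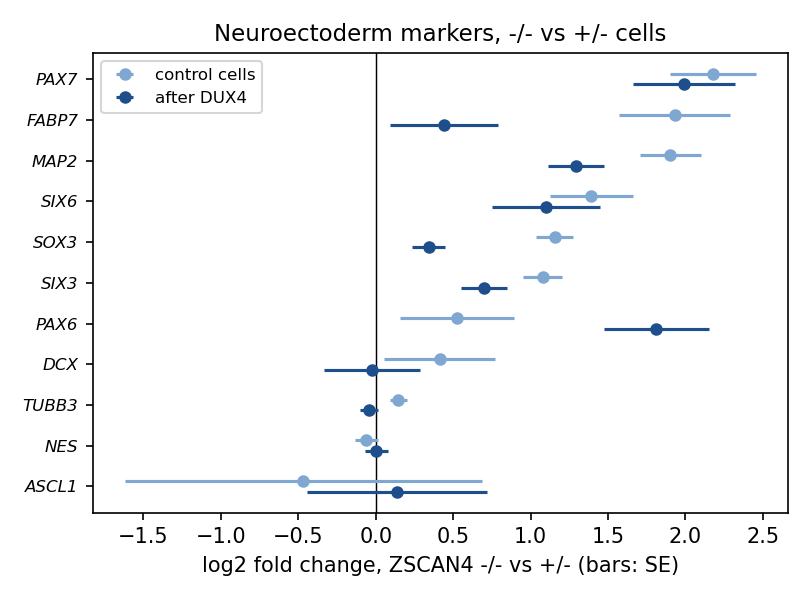
Log2 fold change of -/- against +/- cells for 11 neuroectoderm markers with more than 6 reads over the control groups, in control cells (light) and after DUX4 (dark), with bars for 1 SE of the edgeR fit on 2 libraries per group. PAX7 lies at 2.18 and 1.99, MAP2 at 1.90 and 1.29 and SIX3 at 1.08 and 0.70, while NES lies at -0.06 in controls and near 0 after DUX4.

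No other list was called between the control groups; the next smallest camera adjusted p was 0.0618 for ribosomal protein genes (0 of 39 passed, median 0.08), and all others lay from 0.222 to 0.969. Pluripotency genes had 2 of 29 higher, DUSP6 (0.39 ± 0.07) and SFRP2 (0.25 ± 0.05), and NODAL lower (camera adjusted p = 0.222). Immediate early genes had IER2 (0.36 ± 0.06) and JUND (0.44 ± 0.09) higher. Fibroblast and mesenchymal markers had VIM (0.86 ± 0.07) and FBN1 (1.10 ± 0.23) higher and FN1 (-0.29 ± 0.07) lower. Endoderm markers had FOXA2 higher (0.96 ± 0.24), and the glycolysis list had PKM lower (-0.26 ± 0.05). Among the single-copy DUX4 targets 1 gene, KHDC1, had 32 reads in +/- and 0 in -/- controls and was called lower (edgeR adjusted p = 0.000417), though it overlaps C6orf147. DUSP6, SFRP2, IER2, JUND, FBN1, FN1, FOXA2 and PKM lost their calls without +/- control replicate 1 (adjusted p = 0.134, 0.386, 0.0687, 0.189, 0.0866, 0.348, 0.32 and 0.16), and all but DUSP6 also without +/- control replicate 2 (0.18, 0.0617, 0.15, 0.27, 0.159, 0.319 and 0.166). FOXA2 kept its call only without -/- control replicate 2; without +/- DUX4 replicate 1 or 2, -/- control replicate 1, or -/- DUX4 replicate 1 or 2 its adjusted p was 0.0551, 0.0566, 0.0874, 0.0646 and 0.0646. FBN1 and FN1 lost it without -/- control replicate 2 too (0.083 and 0.057), and SFRP2 without -/- DUX4 replicate 1 (0.0511) or 2 (0.0535). Calls were lost also in DESeq2 for JUND (adjusted p = 0.0612), FBN1 (0.238) and FOXA2 (0.638), in limma-voom for FN1 (0.0502) and FOXA2 (0.0696), and with only the 2 groups compared for SFRP2 (0.128), FBN1 (0.0512), FN1 (0.147), FOXA2 (0.0869) and PKM (0.103). The same held with library totals alone for FOXA2 (0.0505), with the GC and length correction for JUND (0.136) and FOXA2 (0.0573), and with the deposited RPKM for DUSP6 (0.0696), SFRP2 (0.0941), JUND (0.0605), FN1 (0.229), FOXA2 (0.117) and PKM (0.103). The other 17 lists, ribosomal protein genes aside, had 0 members past the threshold over all genes, and their medians lay from -0.21 for naive pluripotency genes to 0.18 for NF-kB genes. For other lists the members higher and lower adjusted over the list alone were as follows: pluripotency (2 and 5), naive pluripotency (0 and 1), heat shock (2 and 0), immediate early (3 and 2) and histone (3 and 0). Further such counts were: ribosomal (1 and 0), telomere (0 and 1), trophectoderm (2 and 1) and fibroblast (2 and 3).

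In controls 114 genes were higher and 54 lower in -/- cells (edgeR adjusted p under 0.05), 32 and 12 by at least 2-fold. An unadjusted p under 0.05 was reached by 1823, and in all 168 called genes both libraries of 1 line lay above both of the other. The counts were 51 and 29 in DESeq2 and 45 and 15 with the deposited RPKM. They moved with single libraries: 33 and 19 without +/- control replicate 1, 35 and 21 without replicate 2, 191 and 118 without -/- control replicate 2, and 438 and 566 without -/- control replicate 1. The -/- control libraries had a chi-square of 4.96 per gene between replicates against 1.83 to 2.09 in the other groups, though the correlation of replicates was lowest in the -/- DUX4 group (0.9889, 0.9898 in the -/- controls). Each genotype is 1 line, so this comparison is between these 2 lines.

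After DUX4, the comparison of the same lines asks what differed once both held RNA of ZSCAN4. Per the labels the allele without GFP is disrupted in -/- cells, but counts per gene do not show which allele the RNA came from. PRTG (2.45 ± 0.19, adjusted p = 4.97e-08), MAP2 (1.29 ± 0.18, adjusted p = 0.000169), CPE (1.32 ± 0.15, adjusted p = 5.79e-06) and PAX7 (1.99 ± 0.33, adjusted p = 0.00148) were again higher in -/- cells. PAX7 was not called without +/- DUX4 replicate 1 (adjusted p = 0.18). ZNF551, a zinc finger gene next to ZSCAN4 (NM_138347, chromosome 19, 58193357 to 58201169, plus strand, hg19), was at 103 ± 3.96 against 33.8 ± 0.381 CPM (1.61 ± 0.10, adjusted p = 4.19e-09). Genes that DUX4 itself raised were higher too: SST, which encodes somatostatin (39.9 ± 1.69 against 14.6 ± 1.01 CPM) and USP29 (15.7 ± 1.72 against 6.21 ± 0.585 CPM). CCBE1 (1.41 ± 0.25) and SLFN13 (1.38 ± 0.24) were among the 10 largest increases too, but neither call held without +/- DUX4 replicate 2 (0.074 and 0.068) or -/- DUX4 replicate 2 (0.0983 and 0.0911). Calls were lost also with the deposited RPKM for MAP2 (adjusted p = 0.0848), PAX7 (0.0644), CCBE1 (0.271) and SLFN13 (0.271).

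Lower genes were again NODAL (-0.95 ± 0.11, adjusted p = 7.01e-06), MCCC2 (-0.94 ± 0.08, adjusted p = 8.14e-08), JRK (-0.85 ± 0.12) and NGRN (-0.79 ± 0.07), and TNFRSF8, which encodes CD30, differed by -0.67 ± 0.07. HMX1 (-0.91 ± 0.19), DACT1 (-0.78 ± 0.15), WDR72 (-0.72 ± 0.13) and PUS7L (-0.69 ± 0.13) were called as well, but each lost its call without -/- DUX4 replicate 2 (adjusted p = 0.187, 0.129, 0.129 and 0.129). HMX1, DACT1 and PUS7L lost it also without +/- DUX4 replicate 1 (0.415, 0.141 and 0.169), DACT1 and WDR72 without +/- DUX4 replicate 2 (0.0809 and 0.0699), and HMX1 and DACT1 without -/- DUX4 replicate 1 (0.227 and 0.163). Calls were lost also in DESeq2 for HMX1 (adjusted p = 0.271), DACT1 (0.14), WDR72 (0.0527) and PUS7L (0.0557), in limma-voom for HMX1 (0.0692), and with the deposited RPKM for JRK (0.144), DACT1 (0.12) and WDR72 (0.145). POU5F1 (-0.06 ± 0.06, adjusted p = 0.867), SOX2 (-0.06 ± 0.07, adjusted p = 0.883) and NANOG (0.03 ± 0.09, adjusted p = 0.968) did not pass.

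Of the 25 lists 6 were called after DUX4. Neuroectoderm markers were higher in 4 of 12, 6 adjusted over the list alone (median 0.39; camera adjusted p = 1.26e-08; adjusted p = 0.0485 with an estimated correlation), with PAX6, the eye and forebrain regulator, at 1.81 ± 0.34. PAX6 was not called without +/- DUX4 replicate 1 (adjusted p = 0.117) or 2 (0.0944) or -/- DUX4 replicate 2 (0.129). Immediate early genes were higher in 3 of 20, 7 with 1 lower adjusted over the list alone (median 0.16; camera adjusted p = 4.81e-07; adjusted p = 0.0485 with an estimated correlation): EGR1 (0.95 ± 0.08), ATF3 (0.32 ± 0.07) and CYR61 (0.30 ± 0.07). Single-copy DUX4 targets were higher in 4 of 19, 5 adjusted over the list alone (median 0.13; camera adjusted p = 1.86e-05; adjusted p = 0.566 with an estimated correlation), namely TPRX1 (0.48 ± 0.08), FAM90A1 (0.47 ± 0.10), CA2 (0.36 ± 0.08) and ZNF296 (0.33 ± 0.06). The fixed list of multicopy targets had 1 of 31 higher, 3 adjusted over the list alone, with USP29 passing over all genes (median 0.09, camera adjusted p = 0.0118, and adjusted p = 0.74 with an estimated correlation). Whether USP29 shares reads with copies was not tested. Endoderm markers had 1 of 6 higher, 2 adjusted over the list alone, with CXCR4 at 0.51 ± 0.08 (median 0.13; camera adjusted p = 0.0158; adjusted p = 0.566 with an estimated correlation). Ribosomal protein genes ranked downward with none called (median -0.05; camera adjusted p = 0.0212; adjusted p = 0.74 with an estimated correlation). Both DUX4 target lists and the ribosomal list lost their calls without +/- DUX4 replicate 1 (adjusted p = 0.319, 0.94 and 0.319) or -/- DUX4 replicate 2 (0.188, 0.457 and 0.2), and the endoderm list without -/- DUX4 replicate 1 (0.327). The multicopy and endoderm calls ended also with no filter (0.258 and 0.317), the endoderm call in limma-voom (0.0831) and the ribosomal call with the deposited RPKM (0.0566). Over all alternatives these 4 ran from 1.64e-09 to 0.319, 1.08e-07 to 0.94, 0.000891 to 0.319 and 0.00019 to 0.327. Of the genes named in this paragraph, ATF3, CYR61, TPRX1, FAM90A1, CA2 and ZNF296 were not called without +/- DUX4 replicate 1 (adjusted p = 0.714, 0.376, 0.221, 0.402, 0.603 and 0.251) or -/- DUX4 replicate 2 (0.554, 0.231, 0.129, 0.243, 0.459 and 0.0911). All of these but TPRX1 were also not called without +/- DUX4 replicate 2 (0.0516, 0.198, 0.186, 0.0512 and 0.0501) or -/- DUX4 replicate 1 (0.163, 0.227, 0.293, 0.114 and 0.138). ATF3, CYR61 and CA2 were also lost without +/- control replicate 1 (0.083, 0.0715 and 0.0659) or 2 (0.0831, 0.0575 and 0.0687). Calls were lost also in DESeq2 for PAX6 (adjusted p = 0.141), ATF3 (0.418), CYR61 (0.239) and FAM90A1 (0.351), in limma-voom for ATF3 (0.0595), and with the GC and length correction for TPRX1 (0.0995). The same held with the deposited RPKM for ATF3 (0.242), CYR61 (0.135), TPRX1 (0.102), FAM90A1 (0.145), CA2 (0.388), ZNF296 (0.0872) and CXCR4 (0.183).

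The other 19 lists had camera adjusted p from 0.0593 for p53 genes, of which CDKN1A was higher (0.58 ± 0.09; adjusted p = 0.113 without -/- DUX4 replicate 2 and 0.065 with the deposited RPKM), and 0.0738 for mesoderm markers, of which EOMES was higher (0.68 ± 0.09) while the median was -0.17, to 0.859 for histones. Within them VIM, a mesenchymal filament gene, was higher by 0.64 ± 0.08 and NODAL was lower. For other lists the members higher and lower adjusted over the list alone were as follows: pluripotency (0 and 2), p53 (2 and 0), stress response (1 and 1), snoRNA host (2 and 0) and DNA methylation (2 and 0). Further such counts were: mesoderm (2 and 0) and fibroblast (1 and 1).

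After DUX4 79 genes were higher and 21 lower in -/- cells (edgeR adjusted p under 0.05), 20 and 5 by at least 2-fold, with 1209 at an unadjusted p under 0.05 and both libraries of 1 line above both of the other in all 100. With the control comparison these shared 27 higher and 15 lower genes, against 0.649 and 0.0818 for independent lists, and 1 gene, PLK2, was lower between controls and higher after DUX4 (0.42 ± 0.07, adjusted p = 0.00206). The second call ended with the deposited RPKM (adjusted p = 0.12) and without +/- DUX4 replicate 1 (0.221) or -/- DUX4 replicate 2 (0.186). DESeq2 gave 46 and 12, and the deposited RPKM 23 and 10. Without +/- DUX4 replicate 1 the counts were 23 and 13, without replicate 2 43 and 13, without -/- DUX4 replicate 1 43 and 14, without replicate 2 28 and 12, without -/- control replicate 1 181 and 77, and without replicate 2 181 and 76.

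The last comparison tests whether the response to DUX4 differed between the lines. Few genes were called, though the simulated test recovered only 44.8% of genes changed by 1.5-fold for this difference. ZNF551 was at 50.6 ± 6.27 CPM in controls and 33.8 ± 0.381 CPM after DUX4 in +/- cells, and at 49.5 ± 8.22 and 103 ± 3.96 CPM in -/- cells, a difference of 1.64 ± 0.14 (edgeR adjusted p = 1.83e-06). PLK2, a polo-like kinase gene, rose more in -/- cells (difference 1.13 ± 0.16, adjusted p = 0.00199), as did PLEKHO2 (0.70 ± 0.11, adjusted p = 0.0068). LOC100652999 and KHDC1 were called on fewer than 70 reads per group and are given only as reads further on. In total 5 genes were higher and 0 lower, with 1106 at an unadjusted p under 0.05; DESeq2 called 4 and 0 and limma-voom 3 and 0. With the deposited RPKM 3 were higher and 1 lower, so that 75% of calls were higher against 100%. The median SE of the difference was 0.163, and for 72.2% of genes the 95% interval of the difference, at 4 degrees of freedom, lay within 1 either way.

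**Figure D4:**
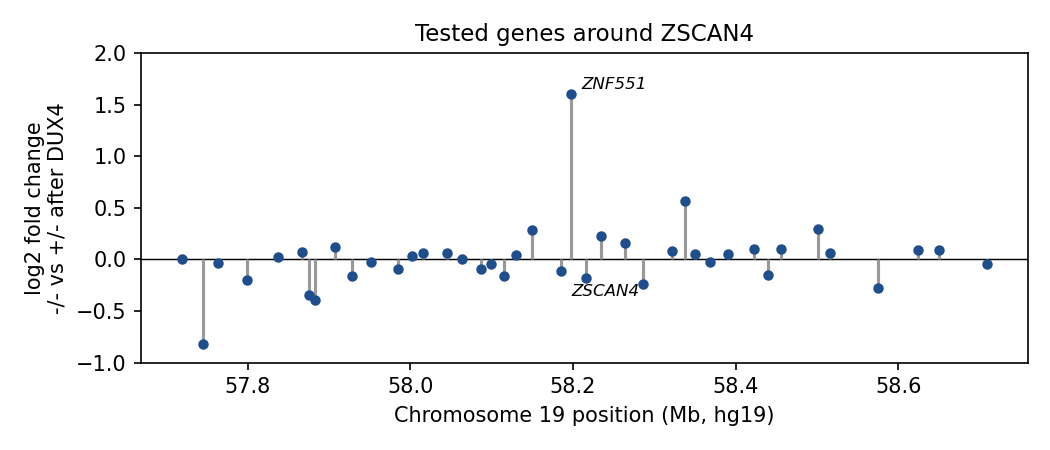
Log2 fold change of -/- against +/- cells after DUX4 for the tested genes around ZSCAN4, by position on chromosome 19 in Mb (hg19), with 1 line and point per gene. ZNF551 stands at 1.61, ZSCAN4 at -0.12, and the largest of the other 39 genes at 0.57.

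Among lists, ribosomal protein genes ranked downward for this difference, with 0 of 39 passing singly (median -0.11, or -0.04 with GC and length trends removed; camera adjusted p = 0.000114; adjusted p = 0.933 with an estimated correlation). Cholesterol synthesis genes (median -0.08; camera adjusted p = 0.048) and neuroectoderm markers (-0.24; 0.048) ranked downward too, with 0 members passing over all genes, 2 neuroectoderm markers lower adjusted over the list alone, and adjusted p = 0.933 with an estimated correlation for each. The ribosomal call ended without -/- control replicate 2 (adjusted p = 0.266; 1.68e-13 to 0.266 over all alternatives). The cholesterol and neuroectoderm calls ended with DESeq2's size factors (0.0668 and 0.0596), library totals alone (0.0532 and 0.0547), the GC and length correction (0.103 and 0.138) and without overlapping genes (0.0504 and 0.0544). The replicate block ended both calls too. The cholesterol call ended also with the stricter filter (0.0536) and the deposited RPKM (0.0712), and the neuroectoderm call in limma-voom (0.124). Both ended without +/- control replicate 2 (0.354 and 0.0949), +/- DUX4 replicate 1 (0.312 and 0.0603) or -/- control replicate 1 (0.225 and 0.626), the cholesterol call also without -/- DUX4 replicate 2 (0.4). Over all alternatives they ran over 0.0142 to 0.4 and 0.00241 to 0.626. The other 22 lists had camera adjusted p from 0.571 for naive pluripotency genes to 0.917 for NF-kB genes. PLK2 was not called in limma-voom (adjusted p = 0.0693) or without +/- control replicate 2 (0.0576), nor PLEKHO2 with the 2-fold threshold, the deposited RPKM (0.165) or without +/- control replicate 1 (0.0772), +/- control replicate 2 (0.0576) or +/- DUX4 replicate 1 (0.101). Over all alternatives PLK2 had 4.71e-09 to 0.0693 and PLEKHO2 6.31e-07 to 0.165. The count of 5 and 0 became 155 and 95 without -/- control replicate 1, 36 and 21 without -/- control replicate 2, and 2 and 0 without either +/- control library. It was 5 and 1 without +/- DUX4 replicate 2, 4 and 1 without -/- DUX4 replicate 1, and 3 and 4 without -/- DUX4 replicate 2. For other lists the members higher and lower adjusted over the list alone were as follows: naive pluripotency (1 and 0), stress response (1 and 0), immediate early (3 and 2), histone (0 and 1) and mitochondrial (1 and 0). Further such counts were: glycolysis (0 and 1) and fibroblast (1 and 0).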

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

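The test of the difference of the DUX4 effects between the lines singled out 5 genes, in that their response differed between the 2 genotypes. ZNF551 differed by 1.64 ± 0.14 (edgeR adjusted p = 1.83e-06), with 50.6 and 33.8 CPM in +/- controls and DUX4 cells and 49.5 and 103 CPM in -/- cells. PLK2 differed by 1.13 ± 0.16 (adjusted p = 0.00199; 11.8 and 157 CPM against 7.22 and 209 CPM), and PLEKHO2 by 0.70 ± 0.11 (adjusted p = 0.0068; 44.4 and 124 CPM against 49.1 and 222 CPM). PLK2 was not called in limma-voom (0.0693) or without +/- control replicate 2 (0.0576), nor PLEKHO2 with the deposited RPKM (0.165), the 2-fold threshold, or without +/- control replicate 1 (0.0772) or 2 (0.0576) or +/- DUX4 replicate 1 (0.101). LOC100652999 had 42 and 0 reads over the +/- controls and DUX4 libraries and 0 and 9 in -/- cells (adjusted p = 0.00988), and was not called without +/- control replicate 1 (0.0645) or 2 (0.0576), +/- DUX4 replicate 1 (0.0815) or -/- DUX4 replicate 2 (0.621). KHDC1 had 32 and 65 reads against 0 and 46 (adjusted p = 0.0449), but it overlaps C6orf147 and was not called in DESeq2 (0.254) or limma-voom (0.0693), with library totals alone (0.0527) or the deposited RPKM (0.457). Nor was it called without +/- control replicate 1 (0.0612) or 2 (0.396), +/- DUX4 replicate 1 (0.129) or 2 (0.0566), or -/- DUX4 replicate 1 (0.0628) or 2 (0.172).

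The tests in the next 3 paragraphs were chosen after the results were seen, but DESeq2 size factors, 1 of the scalings, and leaving out single libraries were planned. ZNF551 starts 2836 bp beyond the end of ZSCAN4 on the same strand. Under 4 other scalings its log2 difference between the lines after DUX4 stayed at 1.478 or above (largest adjusted p = 0.000922), so scaling, depth, GC content and length do not account for it. Nor does a change common to the genes within 500 kb. The other 39 tested genes there had a median of 0.026 (quartiles -0.122 and 0.087). ZSCAN4 was left out of these genes. Their median therefore cannot exclude reads that belong to ZSCAN4, or reads shared with a single neighbour. Beyond that window, USP29 (chromosome 19, 57631509 to 57643293, hg19), which DUX4 raised, was also higher in -/- cells after DUX4 (1.35 ± 0.19). In controls, where ZSCAN4 had 0 and 2 reads in the +/- and -/- groups, ZNF551 differed by -0.032 (95% interval -0.308 to 0.244), a value that both an effect of the edit in cis on transcription running on from ZSCAN4 and loss of the ZSCAN4 protein would give. These explanations cannot be told apart here; reads across the gap between the genes could separate them.

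The 12 tested neuroectoderm markers, 6 of them called higher in -/- controls, had a median log2 difference of 0.801 (quartiles 0.093 and 1.52). A larger share of differentiated cells of every kind does not account for it, as 35 tested markers of 4 other cell types had a median of -0.05 (quartiles -0.251 and 0.245). Nor do GC content and length, since the median was 0.816 once their trends were removed (adjusted p = 2.24e-18). ZSCAN4 had 0 reads over both +/- control libraries, so no ZSCAN4 RNA was measured there that the -/- line could have lost at sampling. Earlier expression of ZSCAN4 was not measured. Because each genotype is 1 line, loss of ZSCAN4 and a difference between the clones cannot be told apart. A drift of 1 clone toward neural genes is possible, and further clones or rescue with ZSCAN4 would test it.

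Of 317 genes that DUX4 raised at least 4-fold in both lines, 28 were higher and 0 lower in -/- than in +/- cells after DUX4, among them EGR1 (0.95 ± 0.08), SST and USP29; the difference of the DUX4 effects was called for 1 of the 28, PLK2. Without +/- DUX4 replicate 1 the counts were 9 and 0, and without -/- DUX4 replicate 2 8 and 1. If a larger share of -/- cells had taken up DUX4 mRNA, and nothing else differed, every induced gene would share 1 shift. Of 198 such genes with at least 5 CPM in +/- DUX4 cells, 77.3% lay above 0 and 32 differed from the common shift of 0.167, 20 above and 12 below. Without +/- DUX4 replicate 1 or 2 it was 14 and 11, and without -/- DUX4 replicate 1 or 2 15 and 20, each with genes on both sides, while the shift ran from 0.074 to 0.253. These differences were taken after DUX4, and the lines also differed in controls, where 168 genes were called. Departures from the shift can thus precede DUX4. For EGR1 the difference of the DUX4 effects was 0.16 and was not called. SST (0.106 and 0.048 CPM in +/- and -/- controls) and USP29 (0 CPM in both) had almost no control reads. Their differences after DUX4 were therefore not there in controls. Their differences of the DUX4 effects, 2.35 and 1.35, were not called, but so few control reads limit that test. As departures of other genes can precede DUX4, the test against the shift cannot tell whether a single factor of uptake accounts for the rest. Such a factor may account for the common shift. With GC and length trends removed, the common shift of the 198 genes was 0.158, against 0.167 before. The 28 called genes had a median of 0.463 after removing those trends and 0.449 before. As they were chosen in these same libraries for being higher, that median says little about GC content and length. The dose of DUX4 per cell stays open, as the DUX4 gene had 0 reads in every library.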

How the results depend on the processing

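Library totals alone, the correction for GC content and length, leaving out overlapping genes, and the deposited RPKM were chosen after the results were seen. The pseudocount alternatives (0.1 and 5) were not run because counts were used. Replicate numbers do not pair the samples: deviations of same-numbered libraries from their group means correlated from -0.041 to 0.043, and with the replicate block 2038 genes were higher and 1320 lower for DUX4 in +/- cells, 2115 and 1602 in -/- cells, 96 and 48 between controls, 74 and 21 between the lines after DUX4, and 7 and 0 for the difference. With it 10 lists were called in -/- cells after DUX4 (13 without it), where pluripotency (adjusted p = 0.0503), trophectoderm (0.0578) and endoderm (0.063) were not, nor cholesterol and neuroectoderm for the difference (0.0629 each). Where 1 library was left out, the lone library of its group was assumed to vary like the other groups. Of the 83 calls of named top genes, 83 held under DESeq2 size factors, library totals alone, and the GC and length correction, 82 with no filter, 79 in limma-voom, 76 in DESeq2, 63 against a 2-fold threshold, 77 of 80 with only the 2 groups compared, 82 with the replicate block, 82 of 82 with the stricter filter, 77 of 77 without overlapping genes, 67 of 81 with the deposited RPKM and 75 to 82 without 1 library; 0 reversed. ZNF551 kept its call under all. For single genes, 6241 results of alternatives were on the same side of the threshold with the same direction, 282 were no longer called, 52 were newly called and 4 reversed; without 1 library the first 3 were 4258, 189 and 74. For called lists, 362 kept their call, 37 lost it and 3 reversed, and without 1 library 265, 30 and 1.

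Counts of higher and lower genes moved by over 1.5 times as follows. For DUX4 in +/- cells (2104 and 1369), DESeq2 gave 586 lower, the 2-fold threshold 605 and 85, library totals alone 1322 and 3426, the deposited RPKM 930 and 4360, and without 1 library 1436 to 2606 and 689 to 1868. For DUX4 in -/- cells (2150 and 1643), DESeq2 gave 648 lower, the 2-fold threshold 663 and 117, library totals alone 1386 and 3975, the deposited RPKM 949 and 5132, and without 1 library 1524 to 2532 and 760 to 1725. Between controls (114 and 54), no filter gave 217 and 135, DESeq2 51 and 29, only the 2 groups compared 61 and 28, the 2-fold threshold 32 and 12, the GC and length correction 85 lower, the deposited RPKM 45 and 15, and without 1 library 33 to 438 and 19 to 566. Between the lines after DUX4 (79 and 21), no filter gave 137 and 60, DESeq2 46 and 12, only the 2 groups compared 199 and 77, the 2-fold threshold 20 and 5, the GC and length correction 144 and 41, the deposited RPKM 23 and 10, and without 1 library 23 to 181 and 12 to 77. For the difference (5 and 0), no filter gave 26 and 21, the stricter filter 3 higher, limma-voom 3 higher, the GC and length correction 10 higher, the deposited RPKM 3 and 1, and without 1 library 2 to 155 and 0 to 95. Of the genes raised at least 4-fold in both lines (28 higher and 0 lower in -/- after DUX4), no filter gave 3 lower, the replicate block 1 lower, only the 2 groups compared 49 and 3, the 2-fold threshold 4 higher, the GC and length correction 2 lower, the deposited RPKM 7 higher, and without 1 library 8 to 42 and 0 to 2. Those that differed from the common shift (32) were 14 in DESeq2, 12 with the deposited RPKM and 11 to 41 without 1 library. The 2-fold threshold lowers counts by construction; for the rest the cause was not tested.

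The number of lists called between controls (1) was 3 with no filter, 2 in DESeq2, 2 in limma-voom and 1 to 4 without 1 library. After DUX4 (6) it was 3 to 8 without 1 library. For the difference (3) it was 1 under DESeq2 size factors, 1 under the replicate block, 1 with library totals alone, 1 with the GC and length correction, 1 without overlapping genes, and 1 to 4 without 1 library. The slope of the DUX4 effects (0.961) was 1.004 with the stricter filter, 1.005 with the deposited RPKM and 0.893 to 0.99 without 1 library. Their correlation (0.908) was 0.956 with the stricter filter, 0.933 with only the 2 groups compared, 0.915 with the GC and length correction, 0.917 without overlapping genes, 0.945 with the deposited RPKM and 0.881 to 0.899 without 1 library. For the endoderm list in -/- cells after DUX4, called upward with a median of -0.50, the rank direction of camera reversed, without a call, with no filter (median 0, adjusted p = 0.805), in limma-voom (-0.50, adjusted p = 0.42) and with the deposited RPKM (-0.63, adjusted p = 0.767). With the deposited RPKM the DUX4 effect reversed for MT-CYB (-0.021) and SPARC (-0.036) in +/- cells and for SPARC (-0.013) and RPS4X (-0.006) in -/- cells, all small rises under TMM. The multicopy DUX4 targets between the lines after DUX4 had a median of -0.01 to 0.173 without 1 library, the lowest without +/- DUX4 replicate 1 (adjusted p = 0.94). The cause was not tested. Depth limits genes with few reads: 3 reads over a group are 0.14 to 0.19 CPM, and the median SE of the difference of effects was 0.163.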

Other observations

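Gene families by shared symbol root, with at least 10 tested members each, were tested only after the results were seen (159 families per comparison; camera adjusted over the families). Zinc finger genes of the ZNF root ranked downward after DUX4: 151 of 496 were lower and 34 higher in +/- cells (median -0.24, adjusted p = 0.0073; adjusted p = 0.12 with an estimated correlation), and 152 lower and 43 higher in -/- cells (median -0.24, adjusted p = 0.0216; adjusted p = 0.186 with an estimated correlation). Protocadherin genes ranked upward, with 7 of 11 higher and 1 lower in each line (medians 1.91 and 1.58, adjusted p = 3.56e-16 and 7.3e-16; adjusted p = 0.12 and 0.186 with an estimated correlation). KLF genes were higher in 7 of 13 in +/- cells and in 8, with 1 lower, in -/- cells (adjusted p = 5.34e-09 and 5.86e-08; adjusted p = 0.12 and 0.186 with an estimated correlation), and histone demethylase genes of the KDM root in 8 and 9 of 20, with 0 and 1 lower (adjusted p = 5.84e-05 and 2.26e-05; adjusted p = 0.423 and 0.416 with an estimated correlation). Of the 159 families 10 were called in each line, 0 between controls, 2 between the lines after DUX4 and 3 for the difference, and 0 with an estimated correlation in any comparison.

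The ribosomal protein list, which ranked downward for the difference of the DUX4 effects (median -0.11, camera adjusted p = 0.000114; adjusted p = 0.933 with an estimated correlation), had a median of -0.04 and an adjusted p of 0.0209 once GC and length trends were removed.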
